A study of Homo sapiens with 56 samples.

How the data were processed

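MCF7 cells were profiled by polyA RNA-seq (26 libraries), GRO-seq (8) and ChIP-seq for ERa or p65 (22 peak lists). Gene values are deposited as signal: per the file headers, HOMER counted reads over whole hg19 RefSeq gene spans, 1 transcript per gene, and scaled them to 10 M tags. The span equalled the listed gene length for 98.8% of genes, so introns were counted. Peak files hold per-library peaks the authors called with HOMER at a false discovery rate of 0.001; only the start and end of each peak (unit other) were used from the deposited peak files, since the score was 1 for every peak. The authors name Bowtie, STAR and HOMER and give no versions.

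Whole reads were recovered from the deposited signal: dividing each library by the smallest step between its values gave whole numbers for 100% of the values up to 200 reads, within a tolerance of 0.05. The scaling is of total tags, so the design's choice of edgeR for counts gave way to limma-trend on log2 of the value + 1; edgeR on the recovered reads was run as an alternative. Depth per library is given with the results. A gene at 1 read per 10 M tags had about 1 or 2 reads in an RNA-seq library and less than 1 in most GRO-seq libraries, so its values carry a counting error as large as themselves.

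Samples were grouped by treatment, experiment and assay as the labels give them; no value column was left without a sample (0 unmatched). Each experiment was fitted with 1 mean per group, using genes with a mean of at least 1 over its libraries, with empirical Bayes moderation with a trend, and Benjamini-Hochberg adjusted p below 0.05 as the threshold. The comparisons, tests, thresholds, gene lists, naming rule and most alternatives were chosen before the data were examined. Differences between effects used 1 fit of all 26 RNA-seq libraries. Replicate numbers were tested for pairing by the correlation of treated and control deviations: it ran from -0.22 to 0.15 in experiment 1, -0.3 to -0.01 in experiment 2, -0.4 to 0.48 in experiment 3 and 0.33 to 0.8 in GRO-seq, so values with the number as a block are given beside the results for GRO-seq. For RNA-seq the block was run as an alternative. Groups of 2 libraries are too small for tests on other groupings of samples.

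Genes were named by a fixed rule. In each contrast with calls these were the 10 largest positive and 6 largest negative changes among genes past the threshold, with both libraries of one group above both of the other and a mean level outside the lowest of 3 equal parts of the tested genes. Up to 4 members of each list with the smallest adjusted p were added, and ESR1, RELA, NFKBIA, TNFAIP3, TFF1, GREB1, PGR, MYC, CXCL12 and CCL20 always. Some further list members are named where they complete a count.

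The 14 lists held 240 genes, all found: oestrogen-induced, oestrogen-repressed, NF-kB feedback and signalling, chemokines and cytokines, immediate early, interferon-stimulated, replication and mitosis, ribosome biogenesis, luminal identity and receptor cofactors, cholesterol synthesis, mesenchymal and basal, apoptosis regulators, markers of other cell types, and stress and RNA quality. Each was tested by camera with an inter-gene correlation of 0.01, adjusted over the 14 lists, and again with the estimated correlation, which is noisy at this size. List members were also adjusted over the list alone.

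Recovery was tested on simulated data with the depth and spread of the libraries and changes in 67, 67 and 66 genes at 1.5, 2 and 4-fold. For E2 in experiment 1 (18154 genes) limma found 82.1%, 91% and 100% of them, for TNFa in experiment 2 (19061 genes) 86.6%, 98.5% and 100%, and for E2 in experiment 3 (19837 genes) 28.4%, 94% and 100%. For E2 in GRO-seq (19596 genes) limma found 0 at each fold with and without the block, and edgeR 1.52% at 4-fold. For contrasts with a common vehicle, 20 simulations with no effect gave the overlap of calls.

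A peak was counted as common to both replicates when peaks overlapped by at least 1 bp. Peaks were assigned to a gene when within 20 kb of its transcription start, with 5 and 100 kb as alternatives. Shares carry exact binomial 95% intervals, which cover counting error only, and were set beside peaks moved by 100 and 200 kb. ERa vehicle replicate 1 and p65 vehicle replicate 2 were called with a 40-fold local threshold and the others with 4-fold. The backgrounds also differed between libraries (none, vehicle or p65 with IL1b). Motifs were not analysed here. The 2 libraries whose title and antibody labels disagree were used in no test, and their overlaps are only described.

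Alternatives were edgeR, quantile normalization, other pseudocounts (0.1 and 5) and filters (none and 5), a minimum change of 1 on the log2 scale, fits with only the 2 groups or with all 26 libraries, a replicate block, leaving out each library, and other peak rules. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, bedtools 2.31.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.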

Results

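MCF7 is a human breast cancer cell line that expresses the oestrogen receptor alpha, ERa, encoded by ESR1. Cells were treated with vehicle, with oestradiol (E2) or with the inflammatory cytokines IL1b and TNFa, and in some groups with the receptor antagonists ICI or TOT or with IKK7, named here as the labels name them. ICI is commonly fulvestrant, TOT 4-hydroxytamoxifen and IKK7 an inhibitor of the kinase that activates NF-kB, but the labels expand none of them and give no doses. Polyadenylated RNA was sequenced in 13 groups of 2 libraries over 3 experiments, nascent RNA (GRO-seq) in 4 groups of 2 libraries, and DNA bound by ERa or by p65, the NF-kB subunit encoded by RELA, was listed as peaks for 22 ChIP-seq libraries. RNA-seq treatments lasted 3 h in experiments 1 and 2 per the labels, which give no time for experiment 3; GRO-seq treatments lasted 30 min and those ChIP-seq libraries with a time 45 min. Whether replicates were independent cultures is not known.

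The RNA-seq tables held 25690 genes, with 6.602 to 21.891 M reads in genes per library. Experiment 1 had vehicle (16.738 and 13.672 M), E2 (16.968 and 16.772), E2+ICI (20.745 and 21.891), IL1b (15.502 and 11.094) and IL1b+ICI (14.274 and 18.347). Experiment 2 had vehicle (14.678 and 13.772), TNFa (13.865 and 13.812) and TNFa+ICI (21.568 and 18.571). Experiment 3 had vehicle (10.813 and 13.655), E2 (14.513 and 10.423), E2+TOT (6.602 and 12.548), E2+TOT+IL1b (12.39 and 11.667) and E2+TOT+TNFa (14.04 and 15.566). The GRO-seq libraries held 4.374 and 1.402 M reads in genes for vehicle, 4.479 and 1.759 for E2, 0.544 and 2.235 for IL1b, and 3.662 and 6.65 for TNFa. Levels below are reads per 10 M tags, as mean ± SD of the 2 libraries of a group, and changes are log2 fold changes from limma with adjusted p.

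Among the RNA-seq libraries, 2 stood apart from their replicate. In experiment 1, genes took 85.5% of the tags of IL1b replicate 2 and 96.9% to 97.9% of those of the other 9 libraries, and the SD of the log2 difference between replicates was 0.44 for IL1b and 0.14 to 0.18 for the other 4 groups. In experiment 3, genes took 73.7% of the tags of E2+TOT replicate 1 and 82.3% to 83.8% of those of the other 9 libraries; that SD was 0.44 for E2+TOT, 0.32 for E2+TOT+TNFa and 0.18 to 0.23 for the other 3 groups. The 2 TNFa+ICI libraries of experiment 2 (97.9% and 97.8%) resembled experiment 1 in this measure, and the other 4 of experiment 2 had 82.8% to 84.8%.

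The first comparison asked which genes E2 changed within 3 h. E2 raised 1684 genes and lowered 1705 of 18344 tested in experiment 1. EGR3, a transcription factor gene, rose the most among the genes named, from 18.9 ± 0.482 to 1005 ± 36.2 (SD, n = 2), a log2 fold change of 5.66 (adjusted p = 6.35e-12). GREB1, a growth regulator and standard oestrogen target, rose from 1602 ± 45.7 to 16216 ± 60.1, and PGR, the progesterone receptor gene, from 7.84 ± 2.02 to 184 ± 12.8 (SD, n = 2). Other large rises were those of NPY1R (3.57), PGLYRP2 (3.07), TGM2 (3.07) and STC2 (2.92). IL1R1, which encodes the receptor for IL1b, fell most (-1.89), followed by the drug-metabolising CYP1A2 (-1.86).

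Of the 30 oestrogen-induced genes on the fixed list, 28 rose and 2 did not pass the test (28 higher adjusted over the list alone), and their median was 1.60. TFF1, a secreted trefoil peptide, rose by 2.50, the growth-promoting MYC by 2.51 and the chemokine CXCL12 by 2.01 (camera adjusted p = 1.39e-46 and adjusted p = 0.0767 with an estimated correlation). Of 12 oestrogen-repressed genes 9 fell, among them TP53INP1 (-1.37), CCNG2 (-1.08) and the cell death gene BMF (-1.27), and HEY2 rose (2.36) (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 2.07e-06 and adjusted p = 0.401 with an estimated correlation). Ribosome biogenesis genes rose in 13 of 15, RRS1 by 0.94 and NOP16 by 0.86 (14 adjusted over the list alone, camera adjusted p = 1.12e-14 and adjusted p = 0.171 with an estimated correlation). Immediate early genes rose in 7 of 17, FOS by 2.61 and EGR1 by 0.86, and KLF6 fell (-0.77) (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.21e-05 and adjusted p = 0.401 with an estimated correlation). Replication genes rose in 9 of 23, CDC6 by 1.04 and CDT1 by 0.82, while CDK1 (-0.39) and MKI67 (-0.36) fell (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00137 and adjusted p = 0.66 with an estimated correlation).

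NF-kB genes went both ways: 9 of 27 fell, such as REL (-1.14), TNFAIP3 (-0.81) and NFKBIA (-0.47), and 3 rose, BIRC3 by 1.44 (5 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.747). Of 16 luminal genes and receptor cofactors, the coactivator genes NCOA2 (-0.93) and NCOA3 (-0.75) and ESR1 itself (-0.43) were among the 6 that fell, and TFAP2C (0.99) among the 4 that rose (5 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.21). VWF was the only one of 7 tested markers of other cell types to change (2.68; camera adjusted p = 0.02 and adjusted p = 0.198 with an estimated correlation). Of the apoptosis regulators PMAIP1 (1.87), CASP7 and BCL2 rose and CFLAR (-0.41), XIAP and BCL2L11 fell (camera adjusted p = 0.747). IFIT2 (1.23) and ISG15 were the interferon-stimulated genes that rose (camera adjusted p = 0.268), SNAI1 (1.49) and CD44 the mesenchymal ones (camera adjusted p = 0.747), CSF1 (-0.44) the 1 chemokine or cytokine that fell (camera adjusted p = 0.747), and HSPA6, listed at 0 with vehicle, the 1 stress gene that rose (camera adjusted p = 0.747). In the cholesterol list DHCR7 rose (0.54) and 2 fell (camera adjusted p = 0.747). Leaving out any one of the 4 libraries left 1343 to 1913 genes called, from 3389.

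E2+ICI against E2 asked which changes ICI opposed. No group had ICI alone. Adding ICI lowered 2124 genes and raised 1735 of 18344 tested. EGR3 fell from 1005 ± 36.2 to 31.8 ± 4.77 (SD, n = 2), PGR from 184 ± 12.8 to 6.15 ± 0.734 and GREB1 from 16216 ± 60.1 to 1871 ± 36.3. NPY1R (-3.55), TFF1 (-2.73), MYC (-2.02) and CXCL12 (-2.01) fell with them, and CYP1A2 (1.98) and IL1R1 (1.83) rose. Of the 30 oestrogen-induced genes 28 fell (28 adjusted over the list alone), with a median of -1.35 (camera adjusted p = 6.72e-37 and adjusted p = 0.112 with an estimated correlation). Of 12 oestrogen-repressed genes 10 rose, TP53INP1 by 1.76, BMF by 1.48 and CCNG2 by 1.24, and HEY2 fell (-1.60) (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.78e-10 and adjusted p = 0.226 with an estimated correlation).

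Replication genes fell in 22 of 23 (22 adjusted over the list alone), CDC6 with -1.97, CDT1 with -1.30 and RRM2, a subunit of ribonucleotide reductase, with -1.03 (camera adjusted p = 3.38e-21 and adjusted p = 0.112 with an estimated correlation). Ribosome biogenesis genes fell in 14 of 15 (14 adjusted over the list alone), NOP56 with -0.94 (camera adjusted p = 5.44e-15 and adjusted p = 0.112 with an estimated correlation). Immediate early genes fell in 6 of 17, FOS with -2.13, and 1 rose (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0043 and adjusted p = 0.541 with an estimated correlation). Interferon-stimulated genes fell in 5 of 15, IFIT1 with -1.44 and ISG15 with -0.69, and 1 rose (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.015 and adjusted p = 0.483 with an estimated correlation). Luminal genes and cofactors rose in 10 of 16, NCOA2 by 0.90 and ESR1 by 0.44, and fell in 4, TFAP2C with -0.79 (10 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.015 and adjusted p = 0.691 with an estimated correlation). NF-kB genes rose in 8 of 27, REL by 1.12, BCL3 by 0.92 and NFKBIA by 0.67, and fell in 3 (8 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0968).

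Against vehicle, added after the data were seen, E2+ICI raised 58 genes and lowered 203 of 18344. GREB1 (0.22, adjusted p = 0.272), TFF1 (-0.22, 0.373) and PGR (-0.29, 0.75) did not pass the test there. EGR3 (0.72) and MYC (0.50) remained above vehicle, and 17 of 23 replication genes were below it, with a median of -0.61. Leaving out any one of the 4 E2 and E2+ICI libraries left 1831 to 1952 genes called, from 3859 in E2+ICI against E2.

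**Figure D1:**
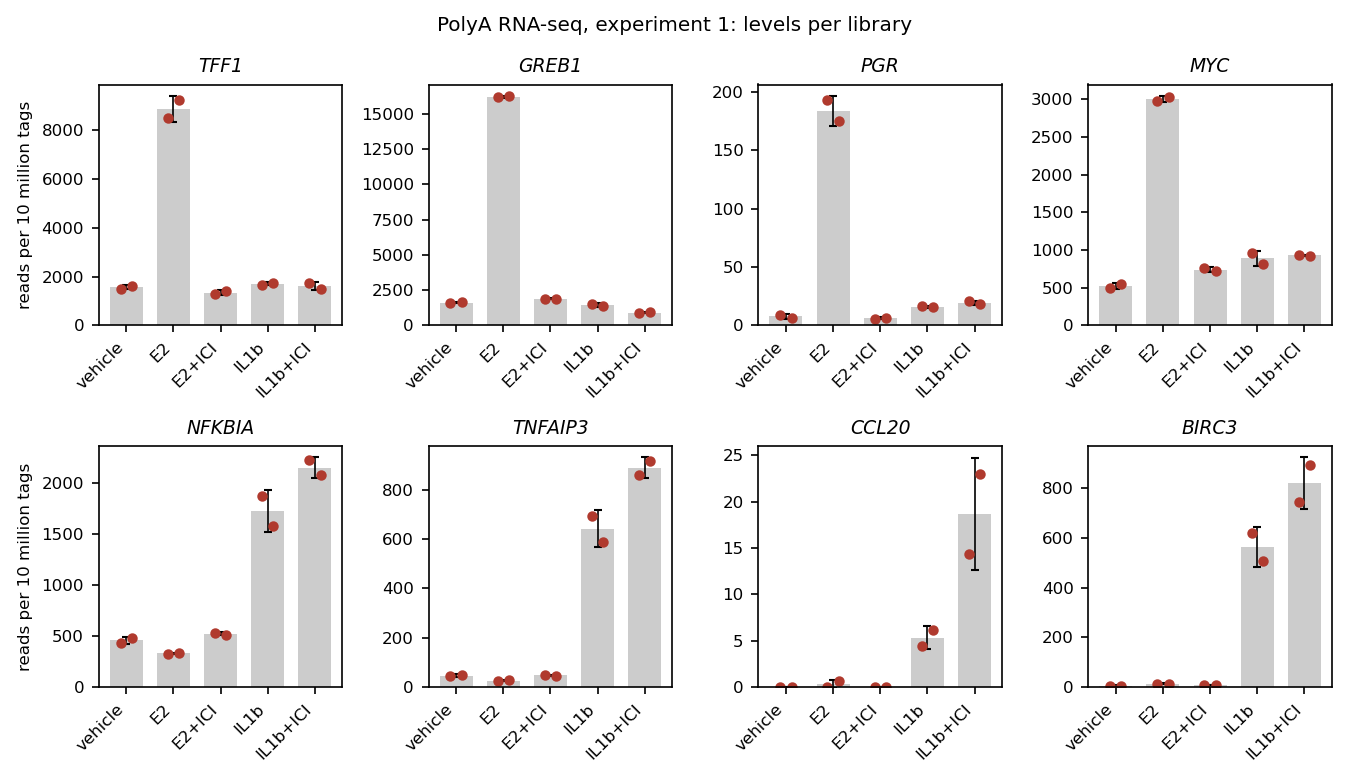
Levels of 8 oestrogen or NF-kB target genes in the 10 RNA-seq libraries of experiment 1, as reads per 10 M tags. Bars are means, lines SD (n = 2) and dots the libraries.

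Experiment 3 repeated E2 against vehicle as the baseline for TOT. E2 raised 1161 genes and lowered 949 of 20078 tested. TGM2, a transglutaminase, rose by 3.61, EGR3 from 75.1 ± 0.83 to 895 ± 9.45 (SD, n = 2), PTGES, a prostaglandin E synthase, by 3.19, and the adrenergic receptor genes ADRA2A and ADRB1 by 3.13 and 3.03. GREB1 rose from 5975 ± 246 to 28344 ± 1065, PGR from 62 ± 2.03 to 427 ± 28.3 and TFF1 from 2120 ± 16.6 to 7345 ± 497 (SD, n = 2). MUM1L1 (-2.38) and TNFRSF11B, which encodes osteoprotegerin, (-2.02) fell, as did ESR1 (-0.72).

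Oestrogen-induced genes rose in 27 of 30 (29 adjusted over the list alone), RET, a receptor tyrosine kinase, by 2.55 and IGFBP4 by 2.30 (camera adjusted p = 1.35e-48 and adjusted p = 0.00717 with an estimated correlation). Oestrogen-repressed genes fell in 8 of 12, CCNG2 with -1.55 and TP53INP1 with -1.44 (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 6.36e-07 and adjusted p = 0.101 with an estimated correlation). Ribosome biogenesis genes rose in 11 of 15, RRS1 by 1.34 (12 adjusted over the list alone, camera adjusted p = 2.44e-11 and adjusted p = 0.0171 with an estimated correlation). Replication genes rose in 5 of 23, CDT1 by 0.80 and MCM2 by 0.49 (8 adjusted over the list alone, camera adjusted p = 0.00315 and adjusted p = 0.446 with an estimated correlation). Immediate early genes rose in 4 of 17, FOS by 0.97, and KLF6 fell (-0.66) (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000596 and adjusted p = 0.279 with an estimated correlation). IFIT1 fell (-1.74), the only one of 15 interferon-stimulated genes to change (camera adjusted p = 0.0173 and adjusted p = 0.708 with an estimated correlation). Luminal genes went both ways, with 5 higher, TFAP2C by 1.17, and 5 lower, NCOA3 with -0.86 (camera adjusted p = 0.485). The DHCR7 gene of cholesterol synthesis rose by 1.16, COL1A1 by 1.38 and LIF by 1.12, each the only called member of its list, and the NF-kB genes REL (-1.01) and NFKBIZ (-0.71) fell. Of the 1683 genes higher with E2 in experiment 1 that were tested here, 861 were higher, and 616 of 1705 lower genes were lower. Leaving out any one of the 4 libraries left 627 to 1038 genes called, from 2110.

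E2+TOT against E2 asked which E2 responses TOT opposed. TOT lowered 1747 genes and raised 784 of 20078; the split depended on the scaling, with 1649 lower and 1352 higher by quantile normalization and 1852 and 1106 by edgeR. EGR3 fell from 895 ± 9.45 to 63.9 ± 5.95 (SD, n = 2), PGR from 427 ± 28.3 to 51.7 ± 7.33, GREB1 from 28344 ± 1065 to 6398 ± 526, TFF1 from 7345 ± 497 to 2016 ± 55.5 and MYC from 1821 ± 81.5 to 349 ± 12. STC2 (-2.48), CXCL12 (-2.39) and the mitochondrial phosphatase gene PPM1K (-2.96) fell as well. Oestrogen-induced genes fell in 27 of 30 (29 adjusted over the list alone, camera adjusted p = 5.64e-43 and adjusted p = 0.00883 with an estimated correlation). Oestrogen-repressed genes rose in 8 of 12, CCNG2 by 1.36 and BMF by 1.21 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.42e-07 and adjusted p = 0.0997 with an estimated correlation).

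Ribosome biogenesis genes fell in 13 of 15, NOP16 with -1.66 and DKC1, the pseudouridine synthase dyskerin, with -1.40 (14 adjusted over the list alone, camera adjusted p = 5.14e-15 and adjusted p = 0.00883 with an estimated correlation). Replication genes fell in 12 of 23, CDC6 with -1.34 (14 adjusted over the list alone, camera adjusted p = 2.57e-08 and adjusted p = 0.11 with an estimated correlation). DHCR7 (-1.23) was among 3 of 13 cholesterol genes that fell (4 adjusted over the list alone, camera adjusted p = 0.0473 and adjusted p = 0.916 with an estimated correlation). FOS (-1.34) and 4 more of 17 immediate early genes fell (camera adjusted p = 0.263). The luminal factors FOXA1 (0.56) and SPDEF (0.72) rose, the adhesion receptor CD44 fell (-1.28), and of 27 NF-kB genes 4 rose (camera adjusted p = 0.938). The genes with the largest rises by the naming rule included SNORD101 (138 ± 153 against 9.5 ± 4.5, SD, n = 2) and LINC00620 (1766 ± 2115 against 166 ± 62.3), whose SD exceeded their mean because E2+TOT replicate 1 carried the signal. DPF3 (2.06) and LIPH (1.86) rose too. Against vehicle, added after the data were seen, 17 genes were called with E2+TOT (5756 at an unadjusted p under 0.05, and 116 by edgeR). Without E2+TOT replicate 2, 6523 genes were called against E2, and without E2 replicate 1 or 2, 934 or 980, from 2531.

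IL1b against vehicle asked what the cytokine did without E2. IL1b raised 1058 genes and lowered 2544 of 18344, and the median of all tested genes moved by -0.13, so list medians are given beside that value. BIRC3, an inhibitor of apoptosis and NF-kB target, rose from 3.94 ± 1.47 to 563 ± 80.7 (SD, n = 2, adjusted p = 2.17e-11), IGFL1, an insulin growth factor-like gene, from 21.7 ± 3.59 to 2197 ± 140, and the chemokine CCL2 from 1.94 ± 0.281 to 162 ± 13.3. The chemokine CCL22 (6.48), the acute phase gene SERPINA3 (5.60), the iodide transporter SLC5A5 (5.14), lymphotoxin beta, LTB (4.14), and LIF (4.02) rose too. BMF (-1.44), IL1R1 (-1.32) and the erythropoietin receptor EPOR (-1.17) fell.

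Of 27 NF-kB genes 19 rose and TRAF1 fell (22 higher and 1 lower adjusted over the list alone, median 1.42 beside -0.13 for all genes). NFKBIA, the inhibitor that NF-kB induces, went from 454 ± 32.1 to 1719 ± 205 (SD, n = 2), TNFAIP3 from 45.7 ± 4.83 to 642 ± 74.3, RELB rose by 3.94 and the adhesion molecule ICAM1 by 3.01 (camera adjusted p = 3.26e-31 and adjusted p = 0.0626 with an estimated correlation). RELA stood at -0.01 (adjusted p = 0.965). Of 15 chemokines and cytokines 10 rose, TNF by 5.61, CSF1 by 2.43 and CCL20, listed at 0 with vehicle, to 5.29 ± 1.24 (10 adjusted over the list alone, camera adjusted p = 1.94e-14, and adjusted p = 0.00552 with an estimated correlation). Of 17 immediate early genes 13 rose, EGR1 by 1.73 and FOSL1 by 2.46 (14 adjusted over the list alone, camera adjusted p = 5.02e-19 and adjusted p = 0.0626 with an estimated correlation). Interferon-stimulated genes rose in 5 of 15, among them the antigen processing genes TAP1 (1.71) and PSMB9 (2.33) (6 adjusted over the list alone, camera adjusted p = 9.16e-05 and adjusted p = 0.21 with an estimated correlation). MMP1, a collagenase, rose by 3.27 and CD44 by 0.44, as 2 of 10 mesenchymal genes (camera adjusted p = 0.00139 and adjusted p = 0.0626 with an estimated correlation). Apoptosis regulators went both ways, PMAIP1 by 1.76 and BCL2 with -0.55, with 3 higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.00128 and adjusted p = 0.365 with an estimated correlation).

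Of the 30 oestrogen-induced genes 11 rose and 6 fell (11 higher and 8 lower adjusted over the list alone), with a median of 0.07 and a mean of 0.25 (camera adjusted p = 0.00067 and adjusted p = 0.423 with an estimated correlation). EGR3 (2.35), RAPGEFL1 (1.75), PGR (0.95), MYC (0.76) and CXCL12 (0.45) rose. GREB1 (-0.16, adjusted p = 0.182), TFF1 (0.12, 0.352) and ESR1 (-0.09, 0.483) did not pass the test. Oestrogen-repressed genes fell in 5 of 12, CCNG2 with -0.71, while EFNA1 rose (2.05) (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0708). Replication genes fell in 9 of 23, CDK1 with -0.65 and MKI67 with -0.49 (13 adjusted over the list alone, median -0.25 beside -0.13 for all genes; camera adjusted p = 0.000557 and adjusted p = 0.406 with an estimated correlation). Ribosome genes rose in 3 of 15, BOP1 by 0.67, and 1 fell (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000557 and adjusted p = 0.365 with an estimated correlation). The share of called genes that were higher was 29.4%; edgeR called 2095 higher and 1617 lower, and quantile normalization 1775 and 2346. Without IL1b replicate 1, 9464 genes were called, and without vehicle replicate 1 or 2, 943 or 1212; without the IL1b replicate 2 that stood apart, 1733 were higher and 1935 lower.

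IL1b+ICI against IL1b asked what ICI changed under IL1b. With no ICI-alone group, its own effect cannot be told from receptor dependence. ICI raised 191 genes and lowered 125 of 18344. EGR1, an immediate early transcription factor, went from 616 ± 58.4 to 1266 ± 35.7 (SD, n = 2, adjusted p = 0.00011), and TGM2 (0.98), FOS (0.95), the stress cytokine GDF15 (0.89) and EGR3 (0.83) rose. MCM10 (-1.61), DTL (-1.34) and the helicase BLM (-1.28), all of DNA replication or repair, fell. PAX3 (0.952 ± 0.59 against 271 ± 369, SD, n = 2) and CDH7 (3.2 ± 2.26 against 513 ± 698) were also called lower, with an IL1b mean below its SD, since IL1b replicate 2 carried their signal.

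Of 17 immediate early genes 6 rose (14 adjusted over the list alone, camera adjusted p = 3.42e-11 and adjusted p = 0.199 with an estimated correlation). Of 23 replication genes 11 fell, CDC6 with -1.20, RRM2 with -0.97 and MCM2 with -0.68 (19 adjusted over the list alone, camera adjusted p = 8.96e-26 and adjusted p = 0.194 with an estimated correlation). ICAM1 was the 1 NF-kB gene of 27 to change, from 1518 ± 177 to 2338 ± 41.7 (SD, n = 2), and 8 were higher adjusted over the list alone (camera adjusted p = 1.53e-06 and adjusted p = 0.456 with an estimated correlation). NFKBIA (0.32, adjusted p = 0.0818) and TNFAIP3 (0.47, 0.0713) did not pass the test. Of the oestrogen-induced genes GREB1 fell from 1440 ± 127 to 907 ± 43.4 (SD, n = 2), while XBP1 (0.50), TIPARP (0.70) and EGR3 rose (camera adjusted p = 0.928), and TFF1 stood at -0.08 (adjusted p = 0.643). Oestrogen-repressed genes rose in 3 of 12, such as CCNG2 (0.54) (8 adjusted over the list alone, camera adjusted p = 4.15e-05 and adjusted p = 0.456 with an estimated correlation). LIF rose (0.78; chemokine list 2 higher adjusted over the list alone, camera adjusted p = 0.0222, and adjusted p = 0.199 with an estimated correlation). ELF3 rose (0.47; luminal list 3 adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.492 with an estimated correlation), OAS2 fell (-2.28), and of the apoptosis and cholesterol lists none was called, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0256 and 0.0256, and adjusted p = 0.492 and 0.492 with an estimated correlation).

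These counts rested on single libraries. Without IL1b replicate 1, 7614 genes were called, without IL1b replicate 2 862 (336 higher, 526 lower), and without IL1b+ICI replicate 1 or 2, 14 or 12; edgeR called 1007 and quantile normalization 840. Against vehicle, added after the data were seen, IL1b+ICI raised 1288 genes and lowered 1640, and 21 of 27 NF-kB genes were higher with a median of 1.38. BIRC3 (7.40), TNFAIP3 (4.26) and NFKBIA (2.24) rose there, GREB1 (-0.82) fell, and 20 of 23 replication genes were lower with a median of -0.73.

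Genes higher with TNFa in experiment 2, which shares no library with this contrast, gave the ICI response. Of 1971 such genes 65 were higher and 5 lower with IL1b+ICI against IL1b, and their median was 0.11, beside 0.07 for the other genes. The 5 lower genes, named after their values were seen, were CYP4F22, DHRS2, E2F7, HSPA1B and THSD4. Of 1151 genes higher with E2 in experiment 3, 21 were lower and 13 higher with ICI on IL1b, against 846 lower with ICI on E2. Without IL1b replicate 2 these counts were 44 lower and 91 higher of the TNFa genes, and 103 lower and 18 higher of the E2 genes.

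TNFa against vehicle asked the same of the other cytokine, in experiment 2. TNFa raised 1999 genes and lowered 3440 of 19288, and the median of all genes moved by -0.11. CCL2 (5.05), SLC5A5 (5.04), LTB (5.00), TNF (4.92), CXCL10 (4.90) and BIRC3 (4.79) were among the largest rises. ICAM1 rose from 331 ± 13.8 to 5817 ± 228 (SD, n = 2), TNFAIP3 from 137 ± 2.82 to 2221 ± 67.9 (adjusted p = 1.3e-14) and NFKBIA from 634 ± 11.9 to 3784 ± 124. CYP1A1 fell by 2.39, and EPS8L3 (-2.47) fell too.

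Of 27 NF-kB genes 24 rose, RELA by 0.72 (24 adjusted over the list alone, median 2.06 beside -0.11 for all genes; camera adjusted p = 2.11e-37, and adjusted p = 0.00975 with an estimated correlation). Of 17 chemokines and cytokines 13 rose, LIF by 2.07, and IL11 fell (-0.40) (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.31e-14, and adjusted p = 0.0349 with an estimated correlation). Immediate early genes rose in 12 of 17, ATF3 by 1.60, and FOSL2 fell (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.14e-08 and adjusted p = 0.142 with an estimated correlation). Ribosome biogenesis genes rose in 14 of 15, NOP16 by 1.06 (14 adjusted over the list alone, camera adjusted p = 1.09e-10 and adjusted p = 0.064 with an estimated correlation). Apoptosis regulators rose in 10 of 13, the death receptor TNFRSF10B by 1.14 and BBC3 by 0.90, and BCL2L1 fell (-0.62) (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.31e-06 and adjusted p = 0.223 with an estimated correlation). Replication genes fell in 12 of 23, E2F1 with -1.05 (15 adjusted over the list alone, median -0.42; camera adjusted p = 0.000457 and adjusted p = 0.248 with an estimated correlation). Interferon-stimulated genes went both ways, IFIT2 by 0.88, TAP1 by 0.64 and MX1 with -0.42, with 5 higher and 2 lower (camera adjusted p = 0.037 and adjusted p = 0.461 with an estimated correlation).

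Of the 30 oestrogen-induced genes 9 rose and 9 fell (the same numbers adjusted over the list alone), with a median of -0.08 and a mean of 0.15 (camera adjusted p = 0.131). MYC (2.54), ELOVL2 (2.12) and KCNK5 (1.74) rose, TFF1 by 0.25 (adjusted p = 0.0451), and GREB1 fell (-0.35); PGR did not pass the test (-0.28, adjusted p = 0.409). Oestrogen-repressed genes fell in 6 of 11, BMF with -2.02, and EFNA1 rose (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0494 and adjusted p = 0.248 with an estimated correlation). The luminal factors SPDEF (-0.88), FOXA1 (-0.78) and GATA3 (-0.43) fell and ESR1 rose (0.30), with 4 of 16 higher and 7 lower (camera adjusted p = 0.416). By edgeR 3007 genes were higher and 2476 lower, and with quantile normalization 2540 and 3001. Without TNFa replicate 1 or 2, 3117 or 3325 genes were called, from 5439.

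TNFa+ICI against TNFa asked the ICI question for TNFa, but its libraries differed in more than ICI. Of 19288 genes 8466 were higher and 4795 lower, and the median of all genes moved by 0.23. Genes of the interferon response were among the lowest: OAS2 (-9.82), XAF1 (-9.35) and MX2 (-9.03), and IFIT2 was 41.1 ± 2.24 against 5028 ± 61.7 (SD, n = 2). CYP1A1 (7.09), the desaturase SCD (4.42) and the sterol sensor INSIG1 (3.22) were higher. All 16 interferon-stimulated genes were lower (median -4.90; camera adjusted p = 2.85e-18 and adjusted p = 0.162 with an estimated correlation), as were 10 of the 17 chemokines, with 1 higher (camera adjusted p = 0.000429 and adjusted p = 0.162 with an estimated correlation). Cholesterol genes were higher in 13 of 13, LDLR by 2.60 (camera adjusted p = 2.63e-06 and adjusted p = 0.298 with an estimated correlation), ribosome genes in 14 of 15, NCL by 2.14 (15 adjusted over the list alone, camera adjusted p = 4.59e-06 and adjusted p = 0.162 with an estimated correlation), and replication genes in 18 of 23, CCNB1 by 2.03 (camera adjusted p = 0.00828 and adjusted p = 0.359 with an estimated correlation). Of 27 NF-kB genes 8 were higher and 11 lower, and of 30 oestrogen-induced genes 13 and 12, with GREB1 at -1.64 and ESR1 at -0.93. TNFAIP3 (-0.09), NFKBIA (0.13), MYC (0.01), TFF1 (0.11) and RELA (0.21) did not pass the test, and the last 4 changed sign with quantile normalization. By edgeR 6801 genes were higher and 6442 lower, and with quantile normalization 6896 and 5397.

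The 2 vehicles differed in the same genes. Vehicle of experiment 2 against vehicle of experiment 1, compared after the data were seen, called 12243 genes, with all 16 interferon genes higher (median 5.53), all 13 cholesterol genes lower (-2.39) and all 15 ribosome genes lower (-1.77). Of 13208 genes called in TNFa+ICI against TNFa and tested there, 12848 (97.3%) moved the way vehicle of experiment 1 did from vehicle of experiment 2. Group and batch could not be told apart within experiment 2. Against the vehicle of experiment 1, whose libraries resemble the TNFa+ICI libraries, TNFa+ICI raised 1682 genes and lowered 2822 genes, among them NF-kB genes (23 of 27 higher, 1 lower, median 1.76), immediate early genes (15 of 17 higher) and replication genes (21 of 23 lower, median -0.93). BIRC3 (6.85), TNFAIP3 (5.49), NFKBIA (3.19), CCL2 (7.13) and MYC (1.56) rose in that comparison, and GREB1 (-0.93) fell. Of 1054 genes higher with IL1b in experiment 1, 343 were lower and 443 higher in TNFa+ICI against TNFa, and of 1058 tested in the difference of the TNFa+ICI effect on that vehicle and the TNFa effect on its own 27 were lower and 97 higher.

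**Figure D2:**
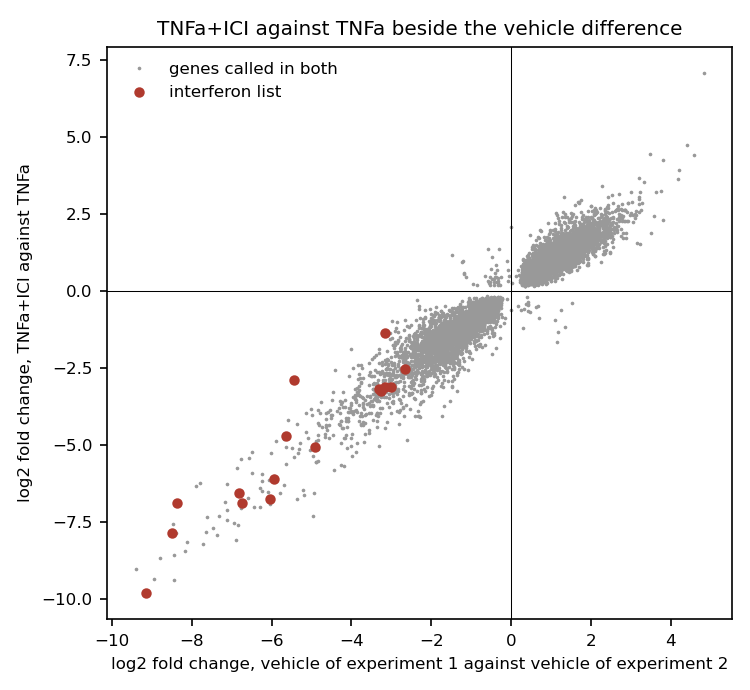
Genes called in TNFa+ICI against TNFa, by their change there and in vehicle of experiment 1 against vehicle of experiment 2. The interferon-stimulated genes are drawn in red.

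E2+TOT+IL1b and E2+TOT+TNFa against E2+TOT asked what a cytokine changed on E2+TOT. With no group of E2+IL1b, E2+TNFa or TOT alone, a rise cannot be tied to TOT. IL1b raised 2463 genes and lowered 1554 of 20078. PGR went from 51.7 ± 7.33 to 523 ± 1.9 (SD, n = 2), where E2 alone gave 427 ± 28.3. GREB1 went from 6398 ± 526 to 23775 ± 1522, with 28344 ± 1065 for E2 alone, and TFF1 from 2016 ± 55.5 to 10074 ± 963, with 7345 ± 497 for E2 alone. EGR3 rose by 2.68, MYC by 2.37 and CXCL12 by 2.25. The cytokine targets IGFL1 (6.07), BIRC3 (12.9 ± 0.66 to 737 ± 51.4), SERPINA3 (5.22) and CCL2 (5.04) rose as well.

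Of the 30 oestrogen-induced genes 28 rose (28 adjusted over the list alone, median 1.48; camera adjusted p = 2.95e-30, and adjusted p = 0.0109 with an estimated correlation). NF-kB genes rose in 19 of 27, ICAM1 by 3.04, TNFAIP3 by 2.98 and NFKBIA by 1.51, and TRAF1 fell (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.53e-17, and adjusted p = 0.0109 with an estimated correlation). Ribosome biogenesis genes rose in 12 of 15, NOP16 by 1.84 (13 adjusted over the list alone, camera adjusted p = 3.29e-11, and adjusted p = 0.0122 with an estimated correlation). Chemokines rose in 8 of 16, TNF by 4.02 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000214 and adjusted p = 0.129 with an estimated correlation). Mesenchymal genes rose in 6 of 9, CD44 by 1.58 and fibronectin, FN1, by 1.11, and TWIST1 fell (camera adjusted p = 0.0335 and adjusted p = 0.155 with an estimated correlation). Oestrogen-repressed genes fell in 5 of 12, BMF with -1.94, with 2 higher (2 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0172 and adjusted p = 0.344 with an estimated correlation). GATA3 (-0.76) and SPDEF (-0.80) fell. Interferon, apoptosis and cholesterol genes were higher in 3, 5 and 3 members (camera adjusted p = 0.0301, 0.0498 and 0.0498 and adjusted p = 0.549, 0.364 and 0.549 with an estimated correlation). Replication genes rose in 2 and fell in 4 (camera adjusted p = 0.353). Without E2+TOT replicate 2, 7503 genes were called, and without E2+TOT+IL1b replicate 1 or 2, 1707 or 1780, from 4017; without the E2+TOT replicate 1 that stood apart, 3602.

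TNFa on E2+TOT raised 2216 genes and lowered 1529 of 20078. CCL2 (5.90), TNF (5.57), BIRC3 (5.41) and LTB (5.10) were among the largest rises, TNFAIP3 went from 46.1 ± 9.94 to 951 ± 47.1 (SD, n = 2), and ADRA2A (4.82) and TGM2 (4.72) rose. PGR went from 51.7 ± 7.33 to 376 ± 74.6 (SD, n = 2), GREB1 to 23470 ± 345, TFF1 to 7433 ± 954, and MYC (2.71), EGR3 (2.77) and CXCL12 (2.01) rose. Oestrogen-induced genes rose in 26 of 30 (26 adjusted over the list alone, camera adjusted p = 2.64e-29, and adjusted p = 0.0117 with an estimated correlation). NF-kB genes rose in 22 of 27 (23 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.35e-23, and adjusted p = 0.00575 with an estimated correlation), and ribosome biogenesis genes in 12 of 15 (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.26e-10, and adjusted p = 0.0156 with an estimated correlation). TAP1 (2.58) was 1 of 4 interferon genes that rose, TNFRSF10B (1.56) 1 of 5 apoptosis genes and KLF10 (0.98) 1 of 7 immediate early genes (camera adjusted p = 0.00452, 0.0134 and 0.024 and adjusted p = 0.455, 0.287 and 0.405 with an estimated correlation). Chemokines rose in 6 of 16 and 1 fell (camera adjusted p = 0.00261 and adjusted p = 0.222 with an estimated correlation). Oestrogen-repressed genes fell in 5 of 12, and EFNA1 rose (2.72; camera adjusted p = 0.0249 and adjusted p = 0.405 with an estimated correlation). FOXA1 (-1.13), SPDEF (-1.34) and TWIST1 (-1.62) fell. Without E2+TOT replicate 2, 7312 genes were called, and without E2+TOT+TNFa replicate 2, 2069, from 3745; without E2+TOT replicate 1, 3347.

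The genes that E2 raised in experiment 1, which shares no library with experiment 3, gave the reach of this effect. Of 1683 such genes, TOT lowered 1016 (median -0.67), IL1b on E2+TOT raised 951 (0.60) and TNFa on E2+TOT raised 818 (0.49); without E2+TOT replicate 1, IL1b raised 896 and TNFa 755. Of the 1074 that neither cytokine raised on vehicle, IL1b raised 443 on E2+TOT and TNFa 345. Against E2 alone, compared after the data were seen, E2+TOT+IL1b differed in 924 genes (614 higher, 310 lower) and E2+TOT+TNFa in 1178 (754 higher, 424 lower). Replication genes were lower in 11 of 23 with IL1b, median -0.60, CDC6 with -1.12, and in 10 with TNFa, median -0.51. Of the oestrogen-induced genes, 10 were lower and 1 higher with IL1b, STC2 with -1.28 and EGR3 with -1.11, while GREB1 (-0.25, adjusted p = 0.515), PGR (0.29, 0.547) and TFF1 (0.45, 0.089) did not pass the test. The cytokines differed from each other on E2+TOT in 126 genes (65 higher with IL1b, 61 lower), with 7 of 27 NF-kB genes lower with IL1b, such as TNFAIP3 (-1.37) and NFKBIA (-1.21), and none of the 30 oestrogen-induced genes called (GREB1 at 0.02).

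**Figure D3:**
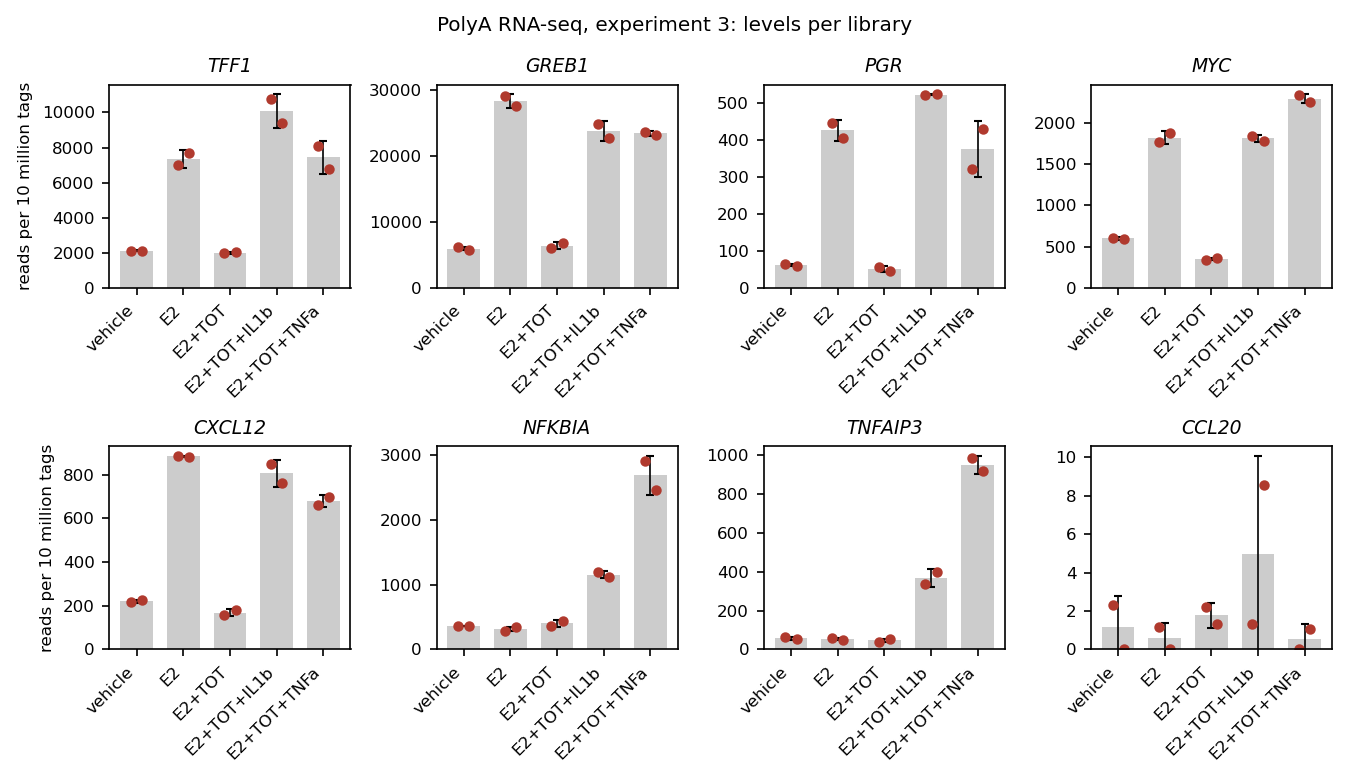
Levels of 8 oestrogen or NF-kB target genes in the 10 RNA-seq libraries of experiment 3, as reads per 10 M tags. Bars are means, lines SD (n = 2) and dots the libraries.

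**Figure D4:**
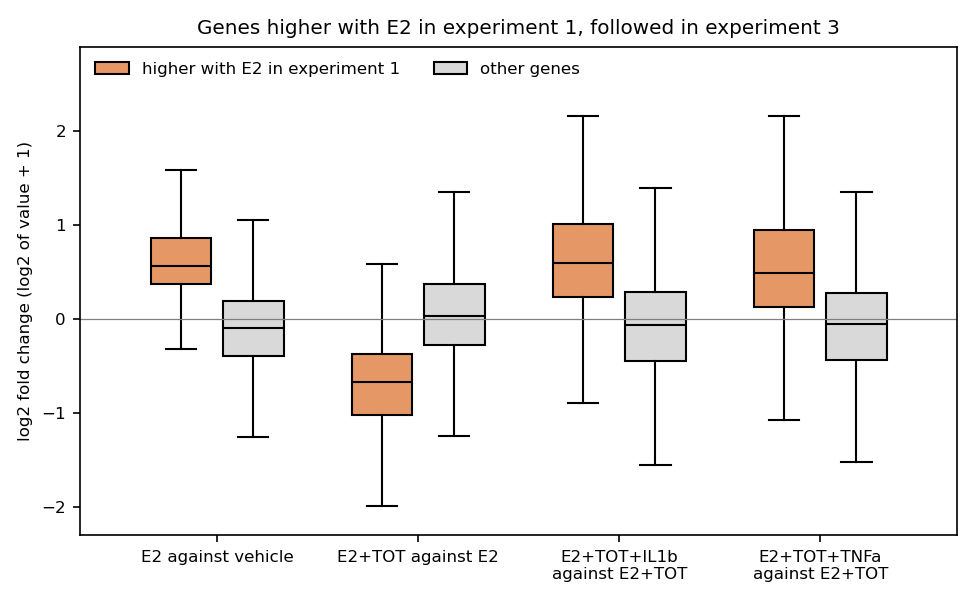
Log2 fold changes in the 4 contrasts of experiment 3 for the genes higher with E2 in experiment 1, beside all other genes. Boxes span the quartiles, and single genes beyond the whiskers are not drawn.

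Tests of the differences between effects used all 26 RNA-seq libraries and 19483 genes. The IL1b effect on E2+TOT differed from that on vehicle in 3226 genes, 2415 higher and 811 lower, and the median moved by 0.13. With quantile normalization 1817 were higher and 1444 lower (median 0.024) and with edgeR 2178 and 1153 (0.045), so the balance depended on the scaling. Of 30 oestrogen-induced genes 25 were higher on E2+TOT, TFF1 by 2.19, GREB1 by 2.05, PGR by 2.37, MYC by 1.62 and CXCL12 by 1.80, as were 11 of 15 ribosome biogenesis genes. Immediate early genes were lower in 8 of 17, EGR1 with -2.04, and NF-kB genes were higher in 4 and lower in 4 of 27 (TNFAIP3 -0.81). The left-out library mattered: 7165 genes were called without E2+TOT replicate 2, 4934 without IL1b replicate 1, and 1636 to 1850 without any one of the other 6 libraries.

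The IL1b and TNFa effects on vehicle differed in 684 genes, 305 higher and 379 lower with IL1b. Of 27 NF-kB genes 11 were lower with IL1b, CD83 with -2.58, NFKBIE with -1.65 and ICAM1 with -1.13, and BIRC3 was higher (2.07). MYC was lower with IL1b (-1.78), and EGR3 (1.18), PGR (1.23), FOSL1 (1.67) and LIF (1.95) were higher. Leaving out 1 library moved the 684, and edgeR called 1201. Cytokine and experiment cannot be told apart. BIRC3 (2.06), LIF (2.1), FOSL1 (1.78), PGR (1.56), MYC (-0.98) and CD83 (-1.14) also differed for TNFa+ICI on the experiment 1 vehicle against TNFa. EGR3, NFKBIE and ICAM1 did not.

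The effects on E2 of TOT (experiment 3) and ICI (experiment 1) differed in 174 genes, 39 higher and 135 lower with TOT. The labels give no dose for either and no time for TOT. PGR (1.67), EGR3 (1.15), GREB1 (0.97) and TFF1 (0.86) were lowered less by TOT than by ICI, and TIPARP (-1.96), CA12 (-1.30), RET (-0.72) and the ribosome gene POLR1B (-0.90) more. The first 4 also had smaller E2 folds in experiment 3 (-1.64, -2.10, -1.09 and -0.71, the last with adjusted p = 0.0569). None passed with E2+TOT against vehicle (PGR -0.26, EGR3 -0.23, GREB1 0.10, TFF1 -0.07), so the smaller fall went with a smaller fold rise. CA12 (1.02) and RET (0.80) had larger E2 folds in experiment 3, as had TIPARP without passing (1.02, adjusted p = 0.0981). None passed with E2+TOT against vehicle (CA12 -0.19, TIPARP -0.63, RET 0.58 with SE 0.13). That contrast called 17 genes, so no return to vehicle is shown. The replication genes E2F1 (0.92), CDT1 (0.76) and TYMS (0.60) were lowered less by TOT. Leaving out 1 library moved the 174, and edgeR called 442 and quantile normalization 445.

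The E2 effect itself differed between experiments 3 and 1 in 44 genes, 25 higher and 19 lower in experiment 3. MYC (-0.92) and FOS (-1.64) had smaller folds there, as had EGR3 (-2.10), PGR (-1.64) and GREB1 (-1.09) from higher vehicle levels. CA12 (1.02), RET (0.80) and IGFBP4 (0.77) had larger folds. Leaving out 1 library lowered the 44, while edgeR called 93 and quantile normalization 150.

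Genes changed by E2 and by a cytokine overlapped. In pairs of contrasts with no shared library, 194 genes were higher with both E2 in experiment 3 and IL1b, against 66.8 by chance (n1 × n2 / N; Fisher's exact test, two-sided p = 5.61e-44), and 338 lower, against 132.1 (p = 1.14e-67). With E2 in experiment 1 and TNFa 497 were higher, against 182.3 (same exact test, p = 7.74e-112), and 580 lower, against 322.3 (p = 4.25e-55), while 259 were higher with E2 and lower with TNFa, against 316.7. The opposite cell also exceeded chance: 267 genes were lower with E2 and higher with TNFa, against 185.6 (same exact test, p = 2.62e-10), and 82 lower with E2 in experiment 3 and higher with IL1b, against 54.7. In experiment 1, where E2 and IL1b share their vehicle, 300 genes were higher with both, 759 lower with both and 131 lower with E2 and higher with IL1b, against 97.1, 236.5 and 98.3 for independent lists, which leave out the shared vehicle. In 20 simulations with no effect, where few genes are called, at most 1 gene was shared, so the part of these overlaps that came from the shared vehicle is not known. The 2 cytokines shared 681 higher and 1210 lower genes across experiments, against 114.7 and 480.8. Genes are not independent replicates, so these p values are too small.

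GRO-seq measured nascent transcription after 30 min. With limma none of 20041 genes passed in any contrast, with 306 genes at an unadjusted p under 0.05 for E2, 960 for IL1b and 713 for TNFa; edgeR without the block also called none. With the replicate number as a block limma called 0, 29 and 57 genes and edgeR 0, 106 and 220. Genes took 73.7% to 76.4% of the tags of each replicate 1 and 98.0% to 104.6% of those of replicate 2 with vehicle, E2 and IL1b, but 80.5% in TNFa replicate 2. The SD of the log2 difference between replicates was 0.53 for TNFa and 1.55 to 1.85 for the others. The block therefore does not remove this difference for TNFa, whose replicate 2 was set against an unlike vehicle library. Of simulated 4-fold changes for E2 limma recovered none at this spread and edgeR 1.52%, so an absent call for E2 says little here. Recovery was not simulated for IL1b or TNFa in GRO-seq, nor with a replicate effect that a block could remove.

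The levels and lists are given as values. With E2 the receptor tyrosine kinase RET was 1034 ± 20.3 against 315 ± 124 (SD, n = 2), with a log2 fold change of 1.77, GREB1 stood at 1.05, NRIP1 at 1.40 and MYC at 1.75 (each adjusted p = 1), and the 30 oestrogen-induced genes had a median of 1.29 (1 higher adjusted over the list alone, camera adjusted p = 4.62e-17 and adjusted p = 0.483 with an estimated correlation).

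With IL1b TNFAIP3 was 3097 ± 1067 against 70.5 ± 57.6 (SD, n = 2; 5.67, adjusted p = 0.125), JUN stood at 2.74, FOSB at 4.08, NFKBIA at 2.58 and ICAM1 at 4.30; CCL20 was listed at 0 in both vehicle libraries, so no fold is given. NF-kB genes had a median of 2.10 (15 higher adjusted over the list alone, camera adjusted p = 1.87e-26 and adjusted p = 0.199 with an estimated correlation), immediate early genes 2.80 (8 higher, camera adjusted p = 5.72e-18 and adjusted p = 0.199 with an estimated correlation) and chemokines 1.91 (1 higher, camera adjusted p = 0.000115 and adjusted p = 0.303 with an estimated correlation). With TNFa the medians were 2.63 for NF-kB genes (19 higher adjusted over the list alone, camera adjusted p = 7.36e-31 and adjusted p = 0.16 with an estimated correlation), 3.05 for immediate early genes (10 higher, camera adjusted p = 5.92e-20 and adjusted p = 0.16 with an estimated correlation) and 3.70 for chemokines (2 higher, camera adjusted p = 8.96e-09 and adjusted p = 0.16 with an estimated correlation). TNFAIP3 stood at 5.64, NFKBIA at 3.46 and MYC at 2.60 with TNFa. These lean in part on vehicle replicate 2, at 29.8, 172 and 67.1 against 111, 1276 and 984 in replicate 1. List medians may too, and with members at 0 in a vehicle library they depend on the pseudocount.

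ChIP-seq asked where ERa and p65 were bound after E2 or a cytokine. The authors called peaks per library with differing thresholds, background libraries and depths, so peak numbers are described and not tested. ERa peaks numbered 856 and 49357 with vehicle, 44245 and 44741 with E2, 15477 and 14516 with IL1b, 16706 and 8419 with TNFa. Single ERa libraries had 9903 with vehicle and IKK7, 6848 with IL1b+IKK7, 12051 with E2+ICI and 29848 with IL1b+ICI. Peaks of p65 numbered 1962 and 514 with vehicle, 858 and 2887 with E2, 23681 and 31224 with IL1b, 3455 and 6809 with TNFa. Peaks of both replicates numbered 19440 for ERa with E2 (43.9% of replicate 1, 95% exact binomial interval 43.5% to 44.4%, and 43.5% of replicate 2), 6538 with IL1b (42.2%, 41.5% to 43.0%, and 45.0%) and 3305 with TNFa (19.8%, 19.2% to 20.4%, and 39.3%), and 3175 for p65 with IL1b (13.4%, 13.0% to 13.8%, and 10.2%) and 1035 with TNFa (30.0%, 28.4% to 31.5%, and 15.2%). ERa vehicle had 251 such peaks, p65 vehicle 14 and p65 E2 12.

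ERa peaks under a cytokine lay largely at sites also bound under E2. Shares here are between peaks found in both replicates unless a library is named. Of the ERa peaks, 87.1% with IL1b (86.3% to 87.9%) and 95.2% with TNFa (94.4% to 95.9%) overlapped an ERa peak under E2, against 0.608% and 0.515% when moved by 100 or 200 kb, and 75.9% of the TNFa peaks overlapped an IL1b peak. Only 79 of the 6538 IL1b peaks overlapped no ERa peak in either E2 replicate. Of the E2 peaks 29.3% overlapped an IL1b peak and 16.2% a TNFa peak. Of the ERa IL1b peaks 25.8% (24.8% to 26.9%) overlapped a p65 peak under IL1b, against 0.103% when moved, but 77.6% a peak of p65 replicate 1 and 35.1% one of replicate 2. Of the p65 IL1b peaks 53.2% overlapped an ERa IL1b peak and 81.1% an ERa E2 peak, but between replicate 2 libraries alone 13.8% and 33.5%, and between replicate 1 libraries alone 41.0% and 81.8%. ERa vehicle replicate 2 covered 69.0% of the ERa IL1b peaks, the single library with vehicle and IKK7 47.2%, with IL1b+ICI 66.4% and with IL1b+IKK7 2.32% (1.97% to 2.72%). The last had 1.2% of its tags in peaks, against 3.71% with vehicle and IKK7, so a weak library and lost binding cannot be told apart. The p65 TNFa peaks were called over a p65 IL1b library at 4-fold, which leaves out sites bound alike under both, so their overlap with p65 IL1b peaks is not given. Of those that remained 21.3% overlapped an ERa TNFa peak.

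The replicates of p65 with IL1b also differed near genes. Of the 28 NF-kB genes 14 and 27 had a peak within 20 kb of the transcription start, against 28.8% and 54.3% of all genes. ERa vehicle replicate 1, with 856 peaks, had one near 14 of the 28, against 2.37% of all genes. For p65 vehicle, replicate 1 with 1962 peaks had one near 18, against 4.53% of all genes, and replicate 2 with 514 peaks near 1, against 0.868%. Near GREB1 there were 7 and 6 ERa peaks with E2, 4 and 4 with IL1b, and 4 and 2 with TNFa. TFF1 had 4 and 4, 2 and 3, and 2 and 2. TNFAIP3 had no p65 peak in IL1b replicate 1 and 3 in replicate 2, and NFKBIA 1 and 4. Of the 30 oestrogen-induced genes 29 and 27 had an ERa peak within 20 kb with E2, 23 and 21 with IL1b, and 24 and 18 with TNFa.

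**Figure D5:**
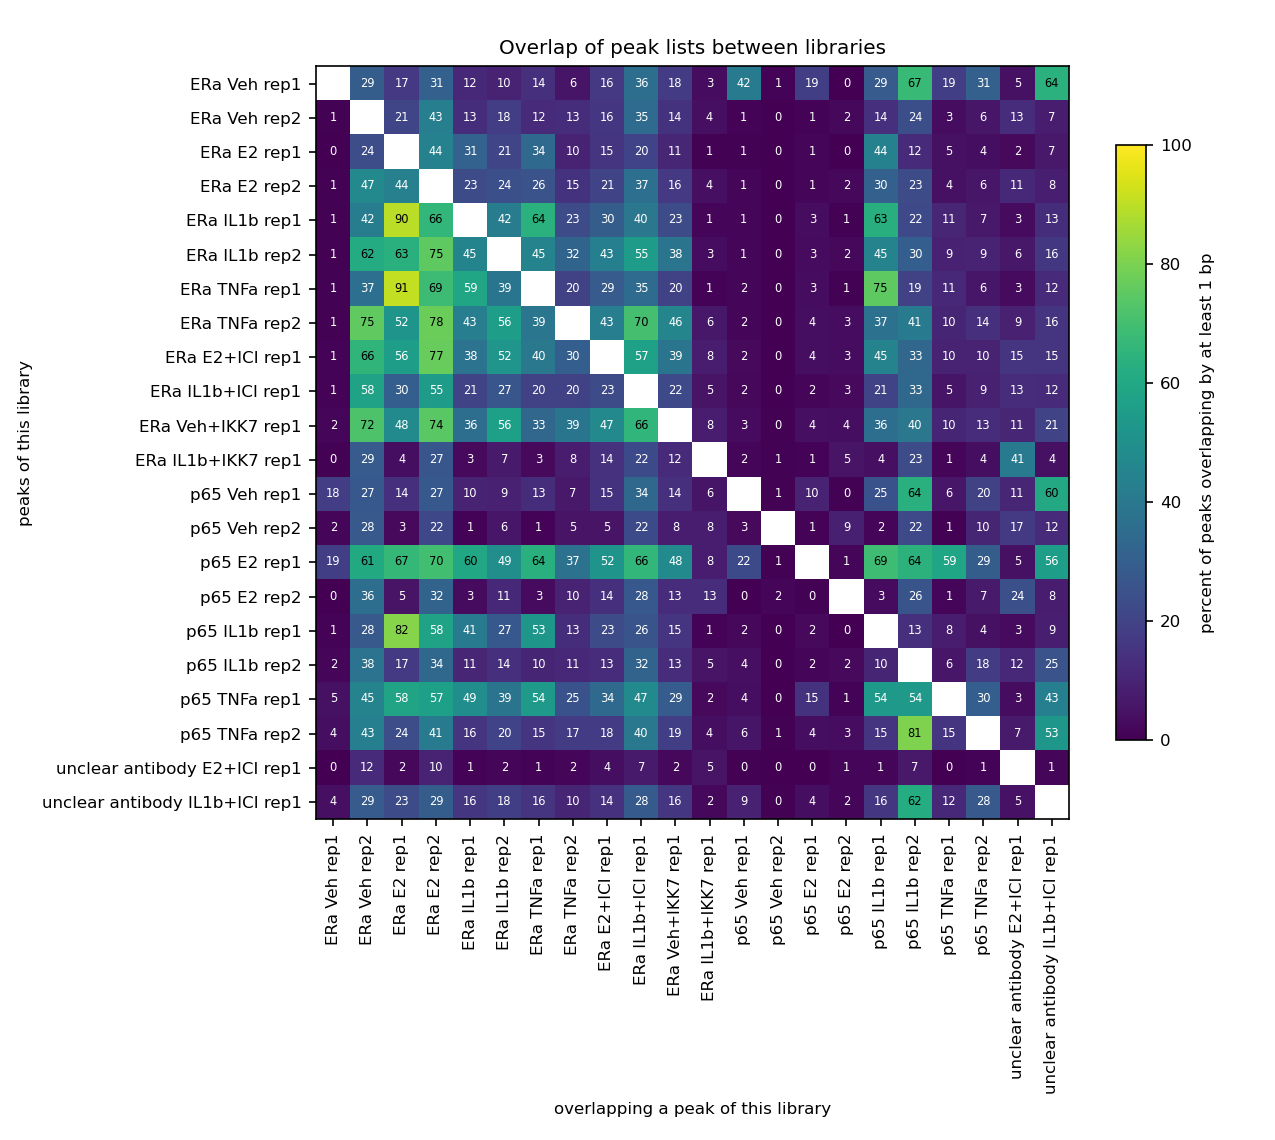
Share of the peaks of each ChIP-seq library (side) that overlap a peak of each other library (foot) by at least 1 bp. The last 2 libraries are those whose title and antibody labels disagree.

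Peaks of both replicates were set against the RNA-seq calls by a two-sided Fisher's exact test, with genes tested and not called as background. ERa peaks under E2 lay within 20 kb of 54.7% of the genes higher with E2 in experiment 1 (921 of 1684), against 35.9%, an odds ratio of 2.16 (adjusted p = 4.08e-49), and of 64.5% in experiment 3, against 34.9%, an odds ratio of 3.38 (adjusted p = 7.43e-86). Genes lower with E2 had odds ratios of 0.841 in experiment 1 (adjusted p = 0.0022) and 0.876 in experiment 3 (adjusted p = 0.0849). Both crossed 1 with other settings, given with the processing. ERa peaks under IL1b lay near 21.0% of the genes higher with IL1b, against 16.7% (odds ratio 1.32, adjusted p = 0.000857), and with replicate 2 alone the odds ratio was 1.05. ERa peaks under TNFa lay near 13.9% of the genes lower with TNFa, against 7.73% (odds ratio 1.93, adjusted p = 1.03e-26), and 10.3% of those higher (1.36, adjusted p = 0.00036). Peaks of p65 lay near 14.1% of the genes higher with IL1b, against 7.69% (1.97, adjusted p = 2.93e-11), and 8.21% of those higher with TNFa, against 3.11% (2.78, adjusted p = 5.19e-23). For lower genes the odds ratios of p65 peaks were 0.981 with IL1b and 1.01 with TNFa (both adjusted p = 0.913), the latter 1.24 and 1.4 with replicate 1 or 2 alone.

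In hg19, EGR3 lies on chromosome 8 (22545174 to 22550815, minus strand), GREB1 on 2 (11674242 to 11782912, plus), ESR1 on 6 (152011631 to 152424408, plus), PGR on 11 (100900355 to 101000544, minus), TFF1 on 21 (43782391 to 43786644, minus) and MYC on 8 (128748315 to 128753680, plus). NFKBIA lies on chromosome 14 (35870716 to 35873960, minus), TNFAIP3 on 6 (138188325 to 138204451, plus), RELA on 11 (65421067 to 65430443, minus), BIRC3 on 11 (102188181 to 102210135, plus), CXCL12 on 10 (44865601 to 44880545, minus) and IGFL1 on 19 (46733009 to 46734500, plus). All are protein-coding genes.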

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

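The tests that weigh explanations were all chosen after the results were seen; the differences between effects were planned.

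Tests of differences described above called 44 genes for E2 in experiment 3 against experiment 1 and 684 for IL1b against TNFa on vehicle. They called 174 for TOT against ICI on E2 and 3226 for IL1b on E2+TOT against IL1b on vehicle. GREB1 (2.05) and TFF1 (2.19) belong to the last, EGR3 (-2.10) to the first, CD83 (-2.58) to the second and TIPARP (-1.96) to the third. All 4 cross experiments, whose vehicles differed in 12243 (experiment 2 against 1) and 11784 genes (3 against 1), and those of IL1b with TNFa and of TOT with ICI also compare different compounds.

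Peaks appeared in 2 ChIP-seq libraries that no test above used, whose titles name p65 and whose antibody labels name ERa: 51895 with E2+ICI and 12781 with IL1b+ICI, above the 1962 and 514 of p65 with vehicle. The IL1b+ICI library covered 77.3% of the p65 TNFa peaks of both replicates, 45.4% of such p65 IL1b peaks and 22.3% of such ERa IL1b peaks, and had a peak within 20 kb of 25 of the 28 NF-kB genes, against 26.5% of all genes. In the E2+ICI library 2.02% and 9.76% of the peaks overlapped a peak of ERa E2 replicates 1 and 2, against 1.03% and 1.45% when moved, and 1.39% and 6.97% one of p65 IL1b replicates 1 and 2, against 0.669% and 1.06%. The antibody of neither was settled.

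The first pattern weighed was the difference of 13261 genes, with the interferon genes among them, between TNFa+ICI and TNFa. For ICI acting on the interferon genes, the TNFa effect on its own vehicle was subtracted from the TNFa+ICI effect on the experiment 1 vehicle. The difference had a median of 0.07 over the interferon list (range -0.72 to 2.53, 1 of 16 called), beside -4.9 in the direct comparison. That baseline presumes that the TNFa+ICI libraries belong with experiment 1. Its vehicle already had a median of -5.53 over this list against the experiment 2 vehicle, so the test cannot decide this question. A batch difference is a candidate explanation: 97.3% of the called genes had the same sign in the vehicle of experiment 1 against that of experiment 2. Header dates also place the TNFa+ICI libraries with experiment 1. ICI acting on the interferon genes or on others stays open because group and batch cannot be told apart.

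The second pattern was the return of E2-induced genes when a cytokine was added to E2+TOT. Against a cytokine effect as large on vehicle, 48.8% of the genes higher with E2 in experiment 3 were called higher in the difference of the IL1b effects, against 10.1% of the others (43.4% and 3.8% without E2+TOT replicate 1). A longer or stronger cytokine treatment in experiment 3 stays open: the NF-kB list had a median difference of -0.03, with quartiles of -0.51 and 0.51, and members went both ways. Cells in which TOT did not act stay open too: 1074 genes higher with E2 and with neither cytokine on vehicle had a median against E2 of -0.15 for E2+TOT+IL1b and -0.25 for E2+TOT+TNFa, which any cause of the return would give, and the rule for this test, with its bound of 0.2, was set and later extended to TNFa after both medians were seen. A cytokine effect on the TOT-bound receptor, or with E2 apart from TOT, is untested and open.

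The third pattern was p65 with IL1b replicate 1, whose peaks lay mostly on ERa peaks. Replicate 2 covered 35.1% of the ERa IL1b peaks (2296 of 6538) and replicate 1 77.6%. This is the pattern itself, so p65 binding at ERa sites as the whole cause stays open. DNA bound by ERa, by a wrong label or by carry-over, stays open: set against other genes, the odds ratio of a peak near the 28 NF-kB genes was 2.47 (95% interval 1.09 to 5.6) in replicate 1 and 3.74 in ERa IL1b replicate 1, and the interval of replicate 2 (22.8, 3.75 to 932) overlapped the first, under a rule set after the counts were seen. Reads of the ERa E2 replicate 1 library are a candidate explanation, since the share of peaks on that library alone was 11.4 times the share on its replicate alone. The ratio was 11.8 for ERa IL1b replicate 1 and 12.5 for ERa TNFa replicate 1, 2.65 and 0.467 for p65 replicate 1 with TNFa and with E2, and 0.0168 to 0.241 for the replicate 2 libraries of these 5 groups, so a batch that follows the replicate number stays open, and p65 at part of these sites as well.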

How the results depend on the processing

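The alternatives chosen after seeing the data were edgeR for the differences between effects, edgeR with the replicate block for GRO-seq, the peak tests within parts of the genes by expression, and the cytokine gene sets without IL1b replicate 2; the others were planned. The rule for odds ratios was changed after results were seen: one on the other side of 1 counts as reversed only where it or the reported one passes the threshold. The numbers of peaks common to both replicates for ERa vehicle, p65 vehicle and p65 E2 are not treated as results.

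Counts of called genes moved by over 1.5 times under several settings. With only the 2 groups in the fit, E2 gave 7121 genes in experiment 1 and 5832 in experiment 3, E2+ICI against E2 7808, IL1b 752, IL1b+ICI against IL1b 29, E2+TOT against E2 614, E2+TOT+IL1b 1472 and E2+TOT+TNFa 2061. These fits take their spread from 4 libraries. With all 26 libraries in one fit the same contrasts gave 1998, 4144, 2351, 1719, 169, 4749, 6199 and 5903 genes. That fit shares 1 spread between experiments, and the cause of its changes was not tested. With a change of at least 1 on the log2 scale, which leaves fewer genes by its construction, they gave 414, 695, 439, 528, 21, 822, 1505 and 1458, TNFa 1163 and TNFa+ICI against TNFa 6844.

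IL1b+ICI against IL1b gave 840 genes with quantile normalization, 1007 with edgeR and 154 with no filter; the cause was not tested. With quantile normalization the difference of the E2 effects gave 150 genes and that of TOT and ICI 445, and with edgeR these gave 93 and 442 and that of IL1b and TNFa 1201; the cause was not tested. In GRO-seq IL1b gave 3 genes with pseudocount 5, 29 with the replicate block and 106 with edgeR and the block, and TNFa gave 57 and 220 with the last 2 settings. The block removes the difference between replicate numbers, though TNFa replicate 2 was unlike the other replicate 2 libraries. In RNA-seq it left each count within 1.5 times, such as 3178 and 2501 for E2 in experiments 1 and 3, 4608 for TNFa and 265 for IL1b+ICI against IL1b.

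In TNFa+ICI against TNFa, TFF1 (-0.33), RELA (-0.23), MYC (-0.43) and NFKBIA (-0.27) reversed with quantile normalization, and MYC (-0.27) with edgeR; the cause was not tested. The other named genes kept their direction where called: of 960 results, 37 were stronger and 11 weaker with quantile normalization, and 36 and 5 with edgeR. None of the 182 list results reversed; 72 lost their call with an estimated correlation.

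The share of TNFa-induced genes higher with IL1b+ICI against IL1b was 3.3%. It was 4.9% for genes picked in the same experiment, 32.1% and 22.8% for genes picked by GRO-seq with IL1b or TNFa, 7.5% with edgeR and 4.6% without IL1b replicate 2. The share lower was 0.3%, and 0.6%, 0%, 0%, 1.9% and 2.2% in the same order; the cause was not tested. The GRO-seq sets hold few genes.

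Leaving out 1 library, where a lone sample is assumed to vary like the other groups, gave 1343 to 1913 genes for E2 in experiment 1, 943 to 9464 for IL1b, 1831 to 1952 for E2+ICI against E2, 12 to 7614 for IL1b+ICI against IL1b and 3117 to 5285 for TNFa. In experiment 3 it gave 627 to 1038 for E2, 934 to 6523 for E2+TOT against E2, 1707 to 7503 for E2+TOT+IL1b and 2069 to 7312 for E2+TOT+TNFa. The differences gave 16 to 32 (E2), 312 to 1525 (IL1b and TNFa), 30 to 4511 (TOT and ICI) and 1636 to 7165 (IL1b on E2+TOT and on vehicle). The highest counts came without IL1b replicate 1 or E2+TOT replicate 2, which left the group to the library that stood apart from its replicate; the cause was not tested. TNFa+ICI against TNFa stayed within 1.5 times (11654 to 11914), and GRO-seq stayed at 0 (306, 960 and 713 genes at an unadjusted p under 0.05 with all libraries, and 0 by edgeR).

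Peaks in either replicate numbered 69546, 23455 and 21820 for ERa with E2, IL1b and TNFa, and 51730 and 9229 for p65 with IL1b and TNFa. Single replicates held 44245 to 44741, 14516 to 15477, 8419 to 16706, 23681 to 31224 and 3455 to 6809, all above the peaks of both by construction.

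Some odds ratios of peaks near genes crossed 1 or the threshold; the cause was not tested. ERa peaks and genes lower with E2 in experiment 1 reversed within 5 kb (1.19) and with peaks in either replicate (1.04), with 0.933 to 1.04 for single replicates. In experiment 3 the odds ratio was 0.76 within 100 kb and 0.867 to 1.17 for single replicates. ERa peaks and genes lower with IL1b gave 1.39 within 5 kb, 1.1 with either replicate and 1.04 to 1.12 for single replicates, and genes higher with IL1b 1.05 to 1.46. Peaks of p65 and genes lower with TNFa gave 1.2 within 100 kb, 1.41 with either replicate and 1.24 to 1.4 for single replicates. The odds ratios for genes higher with E2 or TNFa, and for p65 peaks and genes higher with IL1b, stayed above 1 with adjusted p below 0.05 at 5 and 100 kb, with either replicate and with single replicates, though their size moved (E2 in experiment 3: 3.38, and 5.95 within 100 kb). Within 3 equal parts of the genes by expression, chosen after seeing the data, ERa peaks and genes higher with TNFa did not pass in any part (adjusted p = 0.0903, 0.574 and 0.098 from the lowest), nor p65 peaks and genes higher with IL1b in the lowest (0.255). Each part holds fewer genes. No stricter peak score could be set, since the score was 1 for every peak. GRO-seq had no called genes in the main fit, and genes called with other settings were not set beside peaks.

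GRO-seq was limited by depth (0.544 M reads in genes in IL1b replicate 1) and by spread (SD of the log2 difference between replicates 0.53 to 1.85). In the simulations, 1.5-fold changes were found in 28.4% of the genes in experiment 3 and 82.1% in experiment 1.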

Other observations

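The comparisons in this part were all chosen after the data were seen.

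Genes that E2 raised at least 2-fold in experiment 1 (276 tested in GRO-seq) had a median GRO-seq change of 0.69 with E2 and 0 with IL1b; TNFa is not set beside them, since its replicate 2 was unlike that of vehicle. TNFa against IL1b, fitted only without the replicate block, called 0 genes with limma (789 at an unadjusted p under 0.05) or edgeR. MYC stood at 1.75 with E2 and 1.18 with IL1b, and EGR3 at 1.26 and 3.41, with 9 and 2 reads in vehicle replicate 2.

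Genes were classed by peaks of both replicates under IL1b within 20 kb. Of genes with neither 5.28% were higher with IL1b, with ERa alone 6.12%, with p65 alone 12.4% and with both 9.1%. On E2+TOT the shares higher with IL1b were 11.1%, 16.0%, 17.0% and 20.5%. Within the lowest, middle and highest of 3 equal parts of the genes by expression the odds ratio of ERa peaks under IL1b near genes higher with IL1b was 0.929, 1.61 and 1.28, and that of ERa peaks under E2 near genes higher with E2 in experiment 1 was 2.37, 2.14 and 1.73.

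Vehicle of experiment 3 differed from that of experiment 1 in 11784 genes, with all 13 cholesterol genes lower (median -2.17), 14 of 15 ribosome genes lower (-1.05), and interferon-stimulated genes 1 higher and 5 lower (-0.43).

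The 30 oestrogen-induced genes had an ERa peak within 20 kb in 29 cases in ERa vehicle replicate 2, in 19 with vehicle and IKK7 and in 10 with IL1b+IKK7, each a single library. Of the 79 ERa IL1b peaks above with no ERa E2 peak, 40.5% (29.6% to 52.1%) overlapped a p65 IL1b peak in either replicate. Of the others 86.9% did, largely through the p65 replicate 1 flagged above.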
